A study of Homo sapiens with 12 samples.

How the data were processed

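RNA was measured in T cells enriched for CD3 from human spleen and flow sorted as CD8+ CD45RA− CCR7− CD69+ cells, split by efflux status into efflux(+) and efflux(−) cells, either unstimulated or after 12 h with beads carrying antibodies to CD3, CD28 and CD2. There were 12 libraries in 4 groups of 3, made from poly-A RNA. Groups and conditions were taken from the labels, and replicate numbers from the order of the libraries within a group. Per the submitters' processing notes, reads were aligned to hg19 with TopHat and counted with HTSeq, and DESeq2 was used. Versions and settings of these tools, and the strand that was counted, are not given in the sources used here. The deposited raw table held whole read counts per gene symbol, as the authors made them before any scaling, for 25559 symbols, with no HTSeq summary lines and 0 columns that could not be matched to a library. The deposited normalized table held a signal that was the same raw counts times 1 constant per library, with no log, as checked from the values: divided by the lowest value above 0 of their library, 100% of 306708 values were whole numbers equal to the raw counts within 0.01. Count tests therefore used the raw table.

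Total counts per library ranged from 15904273 to 33954253. Unstimulated libraries of numbers 1 and 2 were the deepest, so all comparisons were repeated with every library thinned to the smallest total. At this depth 1 CPM is about 16 to 34 reads per library. A gene with 3 or fewer counts summed over a group is given by its counts and not by a fitted fold change. Beside them stands an exact interval of its ratio at the 95% level or a fold against a floor of 3 counts. That interval treats summed reads as independent, so it covers counting error only and not the spread between libraries. No 2 libraries of a group were copies of each other: the chi-square per degree of freedom lay between 41.2 and 651, and the Pearson correlation of log CPM across genes between 0.89 and 0.97. Symbols were used as deposited, since no hg19 annotation was at hand: 19690 matched a current name and 5869 did not, and positions of genes were not used here.

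Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, which kept 14078 genes, TMM scaling, a fit with 1 mean per group, and robust quasi-likelihood tests, with Benjamini-Hochberg adjustment over all tested genes of a comparison and a threshold of 0.05. All p-values are two-sided. Adjusted p for single genes are from this edgeR test unless another tool is named. The comparisons were efflux(+) against efflux(−) cells unstimulated, the same after beads, stimulated against unstimulated cells within efflux(+) and within efflux(−) cells, the interaction of these, and the efflux difference averaged over both conditions. Levels are CPM over TMM-scaled totals, as mean ± SD of 3 libraries. Log CPM used a prior count of 2.

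Pairing was checked before calls were compared. Deviations of log CPM from the group means correlated within each of the 6 efflux(+) and efflux(−) pairs with neighbouring title numbers (0.25 to 0.73, median 0.41), and each of the 12 libraries had its title neighbour as best partner within its condition, while other pairs within a condition gave −0.55 to 0.18. Neighbouring titles were therefore treated as pairs in a fit with the replicate block, and its values stand beside a result where they change a call or move a count by more than 1.5 times. The pairing comes from title numbers and these correlations, not from donor names. Across stimulation, libraries with the same place in the order of accessions within their group also deviated together (0.14 to 0.35 in all 12 pairs, others −0.22 to 0.04, best partners of 12 of 12 libraries). This numbering is in no label and was examined only after the data were seen. A replicate block by it is given beside the stimulation results where it changes a call or moves a count as much.

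Gene lists, 32 in all, were fixed before the data were examined, as were the comparisons, the main test, the filters and the rule for naming genes. They covered T cell states, receptors, cytokines, metabolism, handling of tissue and other cell types. A list needed 5 tested members, which left 31; the gamma delta T cell list had 3 and was not tested. An older symbol of PKM was added afterwards. Lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over the 186 tests of 31 lists in 6 comparisons, and again with an estimated correlation and with fry, where the first asks whether a list moves relative to other genes. Counts of members are given over all genes and adjusted over the list alone. No called list differed in sign between its median, its mean and its test.

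Genes were named by a fixed rule. In each comparison it took genes past the threshold with an average log2 CPM over 1 and no overlap between the groups: the 10 highest and 10 lowest fold changes for efflux, or 8 and 8 for stimulation. For the interaction it took the 5 smallest p in each direction where fewer passed. It added up to 4 members of each described list with the smallest p and 15 genes fixed beforehand, such as ABCB1, CD69, ITGAE, PDCD1, IFNG and GZMB. Sex-linked marker genes, HLA and KIR genes, receptor segments, clone names and non-coding RNA were left out of the ranking.

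Alternatives were DESeq2 1.42.0, limma-voom, limma on the deposited normalized values, size factors of DESeq2 or upper-quartile factors in edgeR, no filter, a stricter filter of CPM 5 in 3 libraries, only the 6 libraries compared, each library left out in turn, and the replicate block. Further ones were added after the data were seen. Under the scaling alternatives the median log2 fold change of all genes moved by less than 0.1. The tests were also run on simulated data made from these libraries with 50 genes changed at each of 4 sizes. For the efflux difference at rest, log2 changes of 1, 2, 4 and 6 were found for 8, 66, 72 and 80% of genes with 0 false calls, and with pairing for 54, 78, 88 and 94% with 7 false calls. For the averaged difference the shares were 28, 62, 86 and 96% with 0 false calls, and with pairing 66, 86, 90 and 98% with 9. For stimulation they were 10, 58, 76 and 90% with 5 false calls. When 1 list was raised by a log2 change of 1, it was called (adjusted p = 7.1e-40) together with 1 of 30 other lists. In that simulation genes were drawn independently of each other, with no effect of pairs. It therefore cannot show how often lists of correlated genes are called falsely.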

Results

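Efflux(+) and efflux(−) cells of the CD8+ CD45RA− CCR7− CD69+ memory gate from human spleen were compared by RNA sequencing, unstimulated and after 12 h with beads carrying antibodies to CD3, CD28 and CD2. Each of the 4 groups held 3 libraries. ABCB1, the drug efflux pump MDR1, was at 466 ± 91.6 CPM (counts scaled by library total; mean ± SD, n = 3 throughout) in unstimulated efflux(+) cells and at 5.55 ± 2.86 in efflux(−) cells. After beads its levels were 254 ± 48.7 and 3.82 ± 1.51. Of the 2 other transporters usually tied to dye efflux in lymphocytes, ABCC1 was at 169 ± 24.9 against 168 ± 50 CPM at rest and at 145 ± 11.2 against 144 ± 21.7 after beads. ABCG2 was close to the detection floor, with 115 counts summed over 3 libraries against 0 at rest (at least 36.7-fold against a floor of 3 counts, adjusted p = 0.364) and 55 against 17 after beads (adjusted p = 0.870).

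At rest, genes higher in efflux(+) cells included markers of mucosal-associated invariant T (MAIT) cells and of type 17 lymphocytes. The bicarbonate transporter SLC4A10, a MAIT cell marker, was at 120 ± 128 against 0.753 ± 0.284 CPM (log2 fold change 7.31, adjusted p = 0.0252). Efflux(+) libraries 1, 2 and 3 held 31.7, 62.2 and 266 CPM of it, and its log2 fold change was 5.94 to 7.74 over all alternatives. The receptor for interleukin 23, IL23R, was at 41.8 ± 37.3 against 0.193 ± 0.223 CPM (8.0, adjusted p = 0.0348). The C-type lectin KLRB1 (CD161) was at 151 ± 103 against 8.94 ± 2.75 CPM (4.07, adjusted p = 0.0348). CCL20, a chemokine made by type 17 cells, was at 127 ± 50.9 against 1.51 ± 1.29 (6.33, adjusted p = 0.0168). The gut-homing receptor CCR9 was at 88.0 ± 65.3 against 1.0 ± 0.842 (6.39, adjusted p = 0.0348).

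ABCB1 had the smallest p between resting efflux(+) and efflux(−) cells (log2 fold change 6.38, adjusted p = 1.8e-04). The costimulatory receptor TMIGD2 was at 58.8 ± 38.6 against 0.588 ± 0.350 CPM (6.67, adjusted p = 0.0130). CD160, a receptor of cytotoxic lymphocytes for HVEM, was at 105 ± 50.5 against 14.3 ± 1.64 (2.87, adjusted p = 0.0252). The trophoblast glycoprotein gene TPBG (7.02) and the protease-like gene PRSS35 (6.72) each had an adjusted p of 0.0348. ASIC1, an acid-sensing ion channel listed under its older symbol ACCN2, had 254 counts against 2 over 3 libraries each, a ratio of 122 (adjusted p = 0.0252). Its 95% interval from counting error alone was 33.3 to 1010. KLRC2, which encodes NKG2C, was also higher (4.07, adjusted p = 0.0348), but its close copies KLRC1 and KLRC3 leave the assignment of its reads uncertain. Both genes lower in efflux(+) cells had small fold changes: NINJ2, an adhesion protein gene, at 8.76 ± 1.31 against 32.9 ± 6.78 CPM (−1.91, adjusted p = 0.0349), and ATXN7L1 at 8.81 ± 3.79 against 35.1 ± 9.62 (−2.0, adjusted p = 0.0445).

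In total, 29 of 14078 tested genes passed an adjusted p of 0.05 at rest in edgeR, 27 higher and 2 lower in efflux(+) cells, and 721 had an unadjusted p under 0.05 where 704 would be expected by chance. With the libraries paired by neighbouring title numbers, 287 genes passed, 193 higher and 94 lower, among them all 29, and 1932 had an unadjusted p under 0.05. Pairing brought in HOPX, a factor of effector memory cells (2.14, adjusted p from 0.0659 to 0.00630), the E-cadherin-binding integrin ITGAE (2.58, from 0.223 to 0.00144), and the collagen-binding integrin ITGA1 (2.39, from 0.805 to 0.00935). It also brought in lower levels of the inhibitory receptors PDCD1 (78.5 ± 35.4 against 218 ± 73.4 CPM; −1.48, from 0.169 to 9.0e-04) and CTLA4 (−2.37, from 0.0957 to 7.2e-04). IL17A had 142 counts against 1, 45.4-fold against a floor of 3 counts, with 2.45 ± 3.32 CPM in efflux(+) cells. Its adjusted p moved from 0.276 to 0.0497, and it was not past the threshold in 17 of 19 alternatives. After beads IL17A had 17 counts against 14. ABCG2 remained past no threshold (0.364 and 0.0906). Leaving out efflux(+) libraries 1, 2 and 3 gave 22, 10 and 33 genes, and leaving out efflux(−) libraries 1, 2 and 3 gave 2, 2 and 16. ABCB1 was called in every one of these fits. Without both unstimulated libraries of number 3, which stood apart, 50 genes passed, and 236 with pairing.

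**Figure D1:**
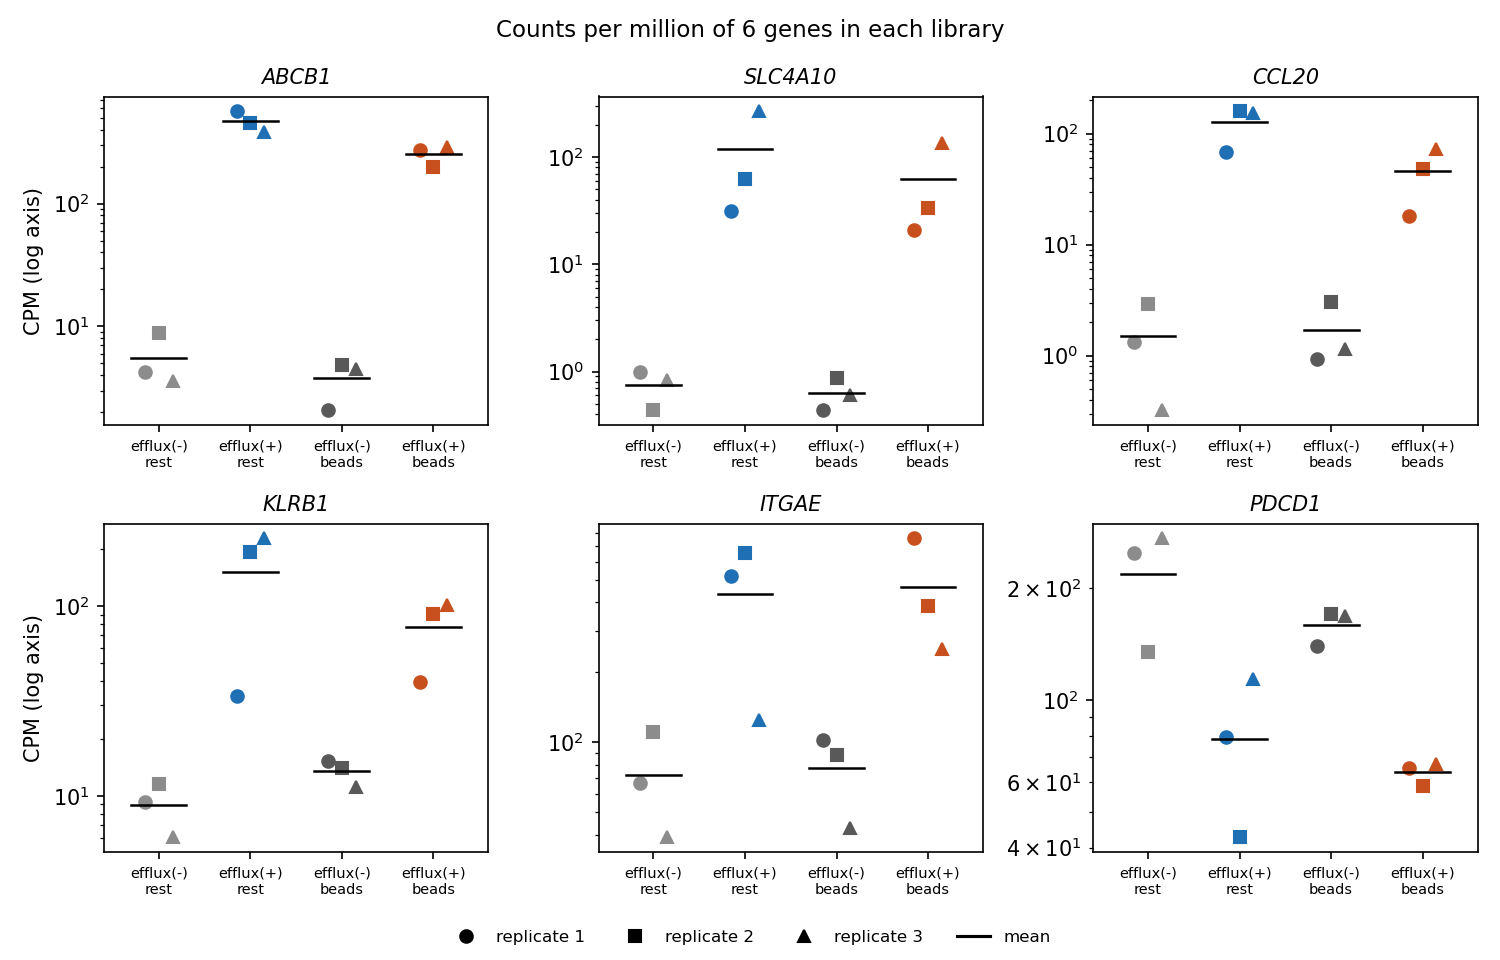
CPM (log axis) of 6 genes in each library of the 4 groups, with the group mean as a bar and replicate numbers as symbols. ABCB1 separates efflux(+) from efflux(−) libraries in both conditions without overlap.

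Among gene lists tested at rest with limma camera, the MAIT marker list stood highest in efflux(+) cells. Its median log2 fold change was 4.07 over 23 genes (adjusted p = 9.0e-27, or adjusted p = 0.241 with an estimated correlation). Over all genes 8 members had risen, 0 had fallen and 15 were not past the threshold. Adjusted over the list alone, 20 had risen, and with pairing 19 of 23 had. SLC4A10 and KLRB1 were examples. The type 17 list had a median of 2.86 over 21 genes (adjusted p = 2.1e-16, 0.241 with an estimated correlation), with 6 risen, 0 fallen and 15 not past, 13 risen when adjusted over the list alone, and 12 risen with pairing. IL23R, CCL20 and KLRB1 were among them, and these lists share 7 genes. The list of NK and innate receptors had a median of 2.07 over 24 genes (adjusted p = 7.7e-13, 0.0250 with an estimated correlation). CD160 and KLRC2 had risen, 22 members were not past the threshold, and 12 had risen when adjusted over the list alone.

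Lower in resting efflux(+) cells was the list of egress and circulation genes, which mark cells able to leave tissue (median −1.28 over 23 genes, adjusted p = 8.5e-09, 0.291 with an estimated correlation). None of its members passed over all genes, 1 had fallen when adjusted over the list alone, and with pairing genes such as CCR7, ITGB2 and SBK1 had fallen. The cell cycle list was lower by a median of −1.02 over 45 genes (adjusted p = 4.0e-07, 0.291 with an estimated correlation), with 0 members past over all genes, 0 over the list alone and 2 fallen with pairing. Both lists kept their call whichever library was left out, but their medians were −0.24 and −0.33 without efflux(−) library 3, and −0.72 and −0.28 without both unstimulated libraries of number 3.

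Smaller shifts at rest depended on single libraries. The cytotoxicity list was lower (median −0.64 over 22 genes, adjusted p = 0.00196, 0.291 with an estimated correlation), with 0 members past over all genes. HOPX had risen when adjusted over the list alone, and with pairing GZMA, GZMK, CST7 and ZEB2 had fallen. Without efflux(+) library 1 its adjusted p was 0.0643 and without efflux(−) library 3 it was 0.0654. Chemokine receptors were lower (median −0.35 over 21 genes, adjusted p = 0.00393, 0.291 with an estimated correlation) although CCR9, the only member past over all genes, had risen. Adjusted over the list alone 3 had risen and 5 fallen, and without efflux(+) library 1 the adjusted p was 0.0627. The chemokine list was higher (median 0.87 over 14 genes, adjusted p = 0.0180, 0.291 with an estimated correlation), with CCL20 risen over all genes and over the list alone. Without efflux(+) library 2 the adjusted p was 0.15 and without efflux(−) library 3 it was 0.167. Immediate-early and dissociation genes were higher (median 0.48 over 34 genes, adjusted p = 0.00948, 0.714 with an estimated correlation), with 0 members past over all genes or over the list alone and 5 risen with pairing. Without efflux(−) library 2 the adjusted p was 0.909 and without efflux(+) library 3 it was 0.720, with the direction of the test turned round in both fits. Without both unstimulated libraries of number 3 it was 2.1e-05.

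ABC transporters as a class were shifted little at rest (median 0.15 over 22 genes, adjusted p = 0.0357, 0.474 with an estimated correlation). ABCB1 alone had risen over all genes, 5 members had risen when adjusted over the list alone, and with pairing ABCB1 and ABCA1 had. The paired adjusted p of the list was 0.0975. Leaving out efflux(−) library 1, efflux(+) library 3 or efflux(−) library 3 gave 0.470, 0.470 and 0.0591.

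With pairing, camera also called T cell receptor activation genes (median 0.55 unpaired, adjusted p from 0.0543 to 2.7e-04) and cytokine receptor genes (0.13, from 0.0695 to 0.0321) as higher and interferon response genes (−0.19, from 0.0651 to 0.0240) as lower in resting efflux(+) cells. With an estimated correlation the paired values were 0.372, 0.416 and 0.571.

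After beads, ABCB1 again had the smallest p between efflux(+) and efflux(−) cells (log2 fold change 6.05, adjusted p = 2.9e-04). KIF5C, a motor protein gene, was at 32.9 ± 2.40 against 6.19 ± 0.430 CPM (2.41, adjusted p = 0.0109), and LRP12, a lipoprotein receptor family gene, at 28.0 ± 4.21 against 2.53 ± 1.27 (3.46, adjusted p = 0.0168). Carbonic anhydrase 2, CA2, was at 22.1 ± 16.4 against 0.401 ± 0.205 CPM (5.75, adjusted p = 0.0168). ASIC1 had 482 counts against 4 over 3 libraries each (6.72, adjusted p = 0.0168), and TMIGD2 remained higher (27.8 ± 11.8 against 0.659 ± 0.299 CPM; 5.37, adjusted p = 0.0384). NINJ2 was lower in efflux(+) cells as at rest (4.78 ± 1.80 against 25.2 ± 2.21 CPM; −2.39, adjusted p = 0.0168).

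These were 7 of the 8 genes that passed after beads in edgeR, 6 higher and 2 lower, with 1280 genes at an unadjusted p under 0.05. Pairing raised the count to 931, with 569 higher and 362 lower, and kept all 8. Among the genes that entered, granzyme B, GZMB, was at 794 ± 484 against 307 ± 243 CPM (1.37, adjusted p from 0.761 to 0.0339), the high-affinity interleukin 2 receptor chain IL2RA at 754 ± 378 against 260 ± 129 (1.53, from 0.369 to 0.0359), and lymphotoxin beta, LTB, at 743 ± 397 against 266 ± 118 (1.48, from 0.428 to 0.00109). The cyclin gene CCND2 was at 868 ± 361 against 266 ± 61.7 (1.71, from 0.0690 to 0.00276). Lower in efflux(+) cells with pairing were granzyme K, GZMK (−1.78, from 0.156 to 0.00108), the memory factor EOMES (−1.80, from 0.105 to 0.0194), the costimulatory receptor CD27 (117 ± 33.1 against 386 ± 68.8 CPM; −1.72), and the inhibitory receptors CTLA4 (−2.83, from 0.0541 to 2.8e-04) and PDCD1 (63.8 ± 4.46 against 159 ± 17 CPM; −1.32, from 0.167 to 0.00146). Without pairing, leaving out efflux(+) libraries 1, 2 and 3 gave 4, 1 and 8 genes, and leaving out efflux(−) libraries 1, 2 and 3 gave 1 gene each time. ABCB1 was called in all 6 fits.

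Ribosome biogenesis had the smallest adjusted p among lists higher in stimulated efflux(+) cells (median 0.72 over 46 genes, adjusted p = 6.1e-26, 0.291 with an estimated correlation). None passed over all genes, but 26 had risen when adjusted over the list alone and 24 with pairing. The nucleolar helicase DDX21 (0.98, adjusted p from 0.133 to 0.00889 with pairing) and WDR43, a small-subunit assembly factor (158 ± 14.2 against 86.5 ± 18.1 CPM; 0.87, from 0.121 to 0.00991), were examples. MAIT markers stayed higher (median 3.46, adjusted p = 1.4e-16, 0.291 with an estimated correlation), with 1 risen, 0 fallen and 22 not past over all genes, 18 risen over the list alone and 20 with pairing. SLC4A10 was at 62.7 ± 61.9 against 0.635 ± 0.214 CPM. The type 17 list had a median of 2.90 (adjusted p = 2.9e-09, 0.291 with an estimated correlation), with 1 risen over all genes, 14 over the list alone and 15 with pairing. NK and innate receptors had a median of 1.52 (adjusted p = 2.4e-06, 0.131 with an estimated correlation), with 0 past over all genes and 9 risen over the list alone. All 4 lists kept their call whichever library was left out.

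Camera called 5 further lists after beads that kept their call in all fits with a library left out. Glycolysis genes were higher in efflux(+) cells, with a median of 0.35 over 25 genes (adjusted p = 8.6e-04, 0.319 with an estimated correlation), with 0 past over all genes, 1 risen over the list alone and 6 with pairing, such as ENO1 (0.83) and the lactate transporter SLC16A1 (1.07). Genes of the unfolded protein response were higher by a median of 0.33 over 28 genes (adjusted p = 7.3e-04, 0.291 with an estimated correlation), with 0 past over all genes or the list alone and 2 risen with pairing. Quiescence and stemness genes were lower (median −0.53 over 29 genes, adjusted p = 8.6e-04, 0.291 with an estimated correlation), with 0 past over all genes and 1 fallen over the list alone. With pairing 7 of them had fallen, among them CD27, CD28, TCF7 and KLF2, and 2 had risen. Markers of CD4+ and regulatory T cells were lower (median −0.90 over 12 genes, adjusted p = 0.00500, 0.291 with an estimated correlation), with 0 past over all genes, 3 fallen over the list alone, and CTLA4, CCR8, CCR4 and TNFRSF4 fallen with pairing. Egress genes were again lower (median −0.79, adjusted p = 0.00593, 0.634 with an estimated correlation), with 0 past over all genes or the list alone and 6 fallen with pairing.

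Chemokine receptors (median −0.51, adjusted p = 0.0236, 0.291 with an estimated correlation) and ABC transporters (median 0.22, adjusted p = 0.0368, 0.481 with an estimated correlation) were the remaining called lists after beads. No chemokine receptor passed over all genes, while 2 had risen and 3 fallen over the list alone, and the paired adjusted p was 0.0919. Without efflux(+) library 1, efflux(+) library 2 or efflux(−) library 2 its adjusted p was 0.0835, 0.0529 and 0.0583. Of the transporters only ABCB1 had risen, over all genes and over the list alone. Without efflux(+) library 1, efflux(−) library 1 or efflux(−) library 3 that adjusted p was 0.0804, 0.0716 and 0.0674.

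With pairing, 4 further lists passed after beads: effector cytokines (median 0.49 unpaired, adjusted p from 0.363 to 0.0196), cytokine receptor genes (0.16, from 0.0516 to 0.00884) and immediate-early and dissociation genes (0.41, from 0.206 to 0.00274) as higher, and cytotoxicity genes (−0.16, from 0.0792 to 0.0240) as lower. With an estimated correlation the paired values were 0.372, 0.365, 0.608 and 0.278. Among cytotoxicity genes, 3 members had risen and 6 had fallen with pairing, GZMB among the former and EOMES, GZMK and CST7 among the latter.

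P-values of the averaged difference, with or without pairing, take unstimulated and stimulated libraries as independent. Libraries of the same number deviated together across stimulation, so these p-values may be too small. The 6 pairs may likewise not be 6 separate samples. Averaged over both conditions, ABCB1 differed by a log2 fold change of 6.22 (adjusted p = 4.8e-06) and was higher in efflux(+) cells in 6 of 6 pairs. SLC4A10 (6.96, adjusted p = 0.00123), CCL20 (5.54, adjusted p = 0.00108), CCR9 (6.26) and IL23R (6.67, adjusted p = 0.00305) were all higher. The stem cell factor receptor KIT had 164 counts in unstimulated efflux(+) cells and 0 in efflux(−) cells, 52.4-fold against a floor of 3 counts, and 17.2 ± 11.3 against 0.0923 ± 0.0905 CPM after beads (adjusted p = 0.00395). ZBTB16, the factor PLZF of innate-like T cells, was higher by 4.28 (adjusted p = 0.0483), IL18RAP, a chain of the interleukin 18 receptor, by 4.11, and ITGAE by 2.58 (adjusted p = 0.0147).

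Lower in efflux(+) cells over both conditions were CTLA4 (−2.60, adjusted p = 0.00373), PDCD1 (−1.40, adjusted p = 0.0131), the skin-homing receptor CCR4 (−2.79, adjusted p = 0.00831), NINJ2 (−2.15, adjusted p = 0.00108), the inhibitory receptor FCRL3 (−1.97), the chromatin regulator ARID5B (−1.76), EOMES (−1.48, adjusted p = 0.0133), and the exhaustion-linked factor TOX (−1.15). By this test 183 genes passed in edgeR, 134 higher and 49 lower, and 1212 with pairing (733 higher, 479 lower), with all 183 among them. GZMK (−1.28, adjusted p from 0.0726 to 2.7e-04), ITGA1 (2.04, from 0.227 to 0.00109) and IL2 (1.18, from 0.507 to 0.00555) entered with pairing. The unpaired count was 108 without stimulated efflux(−) library 1, 97 without stimulated efflux(−) library 2, 120 without stimulated efflux(−) library 3 and 113 without stimulated efflux(+) library 2. It ranged from 122 to 269 in the other 8 fits and was 425 without both unstimulated libraries of number 3.

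List tests of the averaged difference placed MAIT markers (median 3.78, adjusted p = 6.0e-25, 0.241 with an estimated correlation), type 17 genes (3.30, adjusted p = 2.3e-14, 0.241 with an estimated correlation) and NK and innate receptors (2.13, adjusted p = 3.7e-11, 0.0250 with an estimated correlation) at the top by median. Of 23 MAIT markers 16 had risen over all genes and 21 over the list alone, with 0 fallen. Type 17 genes had 11 risen and 10 not past, with 16 risen over the list alone, and NK receptors 7 risen and 17 not past, with 15 risen over the list alone. Ribosome biogenesis was higher by a median of 0.43 (adjusted p = 1.9e-14, 0.353 with an estimated correlation), with 0 members past over all genes, 3 risen over the list alone and 17 with pairing. Egress genes were lower (−1.09, adjusted p = 8.6e-07, 0.348 with an estimated correlation), with SAMD3 fallen over all genes, 10 fallen over the list alone, and a median of −0.44 without unstimulated efflux(−) library 3. Chemokine receptors were lower (−0.67, adjusted p = 0.00281, 0.291 with an estimated correlation), with CCR9 and CCR6 risen, CCR8, CCR4 and S1PR4 fallen, and 3 risen and 9 fallen over the list alone. Cytotoxicity genes were lower (−0.46, adjusted p = 0.00374, 0.319 with an estimated correlation), with HOPX risen, EOMES fallen, and 1 risen and 4 fallen over the list alone. These 7 lists kept their call whichever library was left out.

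Another 7 lists passed for the averaged difference but not in every fit with a library left out. Cell cycle genes were lower (−0.49, adjusted p = 0.00393, 0.490 with an estimated correlation), with 0 past over all genes, 4 fallen over the list alone, and a median of −0.20 (adjusted p = 0.0563) without unstimulated efflux(−) library 3. The unfolded protein response was higher (0.20, adjusted p = 0.00447, 0.319 with an estimated correlation), with 0 members past either way and 0.0573 without unstimulated efflux(−) library 3. Quiescence genes were lower (−0.28, adjusted p = 0.0150, 0.320 with an estimated correlation), with CD27 fallen, 2 fallen over the list alone, 0.0944 without unstimulated efflux(+) library 1 and 0.0848 without unstimulated efflux(−) library 3. ABC transporters were higher (0.14, adjusted p = 0.0231, 0.433 with an estimated correlation), with ABCB1 risen, 5 risen over the list alone, 0.176 without unstimulated efflux(−) library 1 and 0.159 without unstimulated efflux(+) library 3.

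Markers of CD4+ and regulatory T cells were lower over both conditions (−0.51, adjusted p = 0.0240, 0.291 with an estimated correlation), with CTLA4, CCR8 and CCR4 fallen over all genes and 2 risen and 4 fallen over the list alone. Its adjusted p was 0.0991, 0.0673 and 0.0654 without unstimulated efflux(+) library 1, efflux(+) library 3 and efflux(−) library 3. Cytokine receptor genes were higher (0.09, adjusted p = 0.0335, 0.490 with an estimated correlation), with IL23R, IL18RAP, IL12RB2 and IL2RA risen, TGFBR3 fallen, and 10 risen and 2 fallen over the list alone. Without unstimulated efflux(+) library 3, unstimulated efflux(−) library 3, stimulated efflux(−) library 1 or stimulated efflux(+) library 3 its adjusted p was 0.0865, 0.130, 0.0716 and 0.0967. Immediate-early and dissociation genes were higher (0.56, adjusted p = 0.0224, 0.773 with an estimated correlation), with 0 past either way and 14 risen with pairing. That adjusted p was 0.377, 0.576 and 0.0744 without unstimulated efflux(−) library 2, unstimulated efflux(+) library 3 and stimulated efflux(+) library 2.

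With pairing, effector cytokines (median 0.65 unpaired, adjusted p from 0.248 to 0.0117), chemokines (0.47, from 0.176 to 0.0193) and glycolysis genes (0.23, from 0.0596 to 0.00884) also passed as higher for the averaged difference. With an estimated correlation the paired values were 0.360, 0.298 and 0.314.

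**Figure D2:**
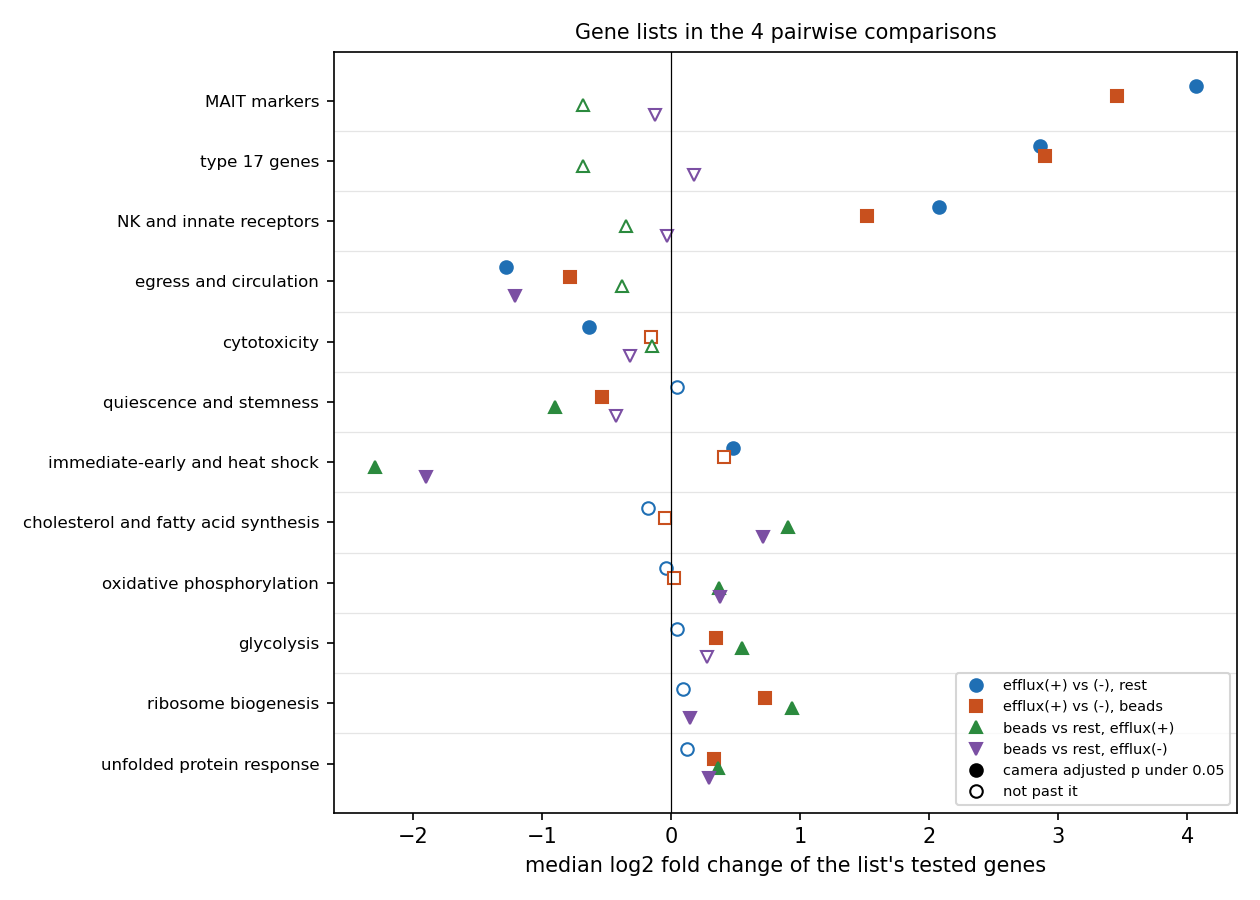
Median log2 fold change of the tested genes of each list in the 4 pairwise comparisons, filled where the camera adjusted p at the preset correlation was under 0.05. MAIT, type 17 and NK receptor lists lie to the right in both efflux comparisons, and ribosome biogenesis is filled after beads and not at rest.

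The difference between efflux(+) and efflux(−) cells at rest resembled that after beads. ABCB1, ASIC1, TMIGD2 and NINJ2 were called in both conditions, and all 6 genes higher after beads were among the 27 higher at rest. Across all tested genes the log2 fold changes had a Pearson correlation of 0.50 (Spearman 0.34), and all 29 genes called at rest and all 8 called after beads kept their direction in the other condition. With pairing, 136 genes were higher in both conditions, against 7.80 for independent lists, and 60 were lower in both, against 2.42. The values for independent lists leave out that libraries of the same number deviated together across stimulation. PRSS35 (6.72 at rest, 6.61 after beads), CCR9 (6.39, 6.14), ITGAE (2.58, 2.58) and PDCD1 (−1.48, −1.32) were among the genes with close values.

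**Figure D3:**
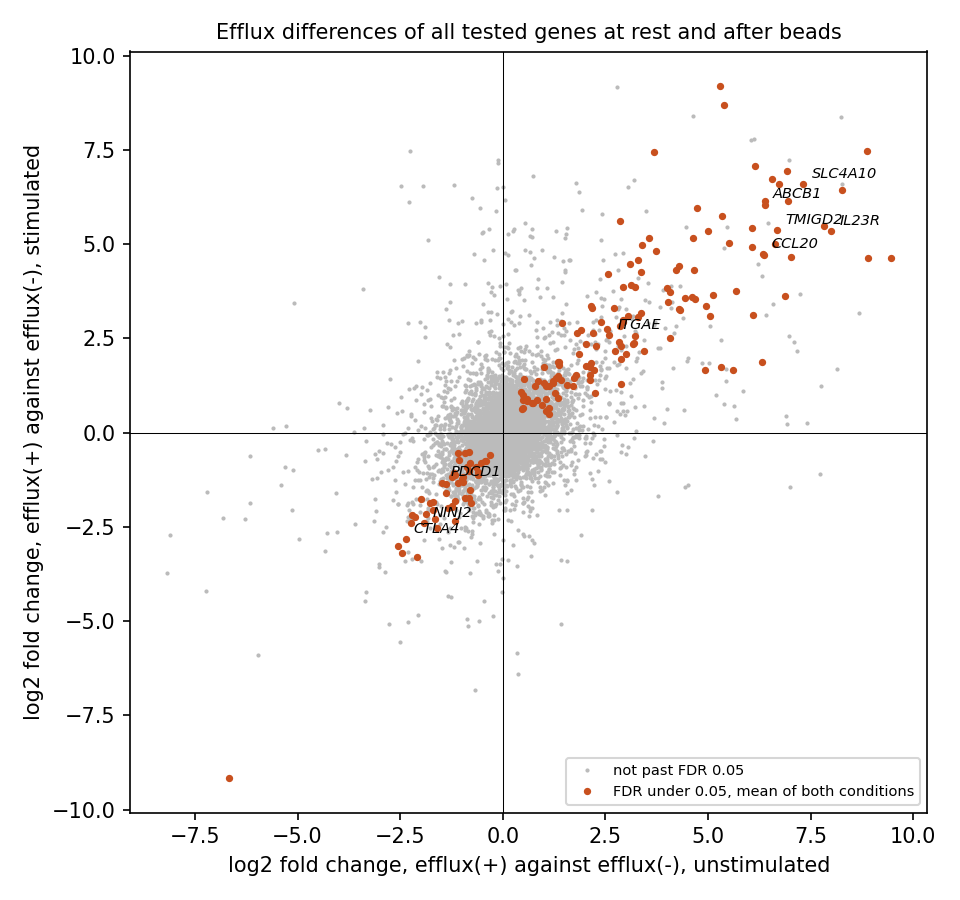
Log2 fold change of efflux(+) against efflux(−) cells for all tested genes, unstimulated on the horizontal axis and stimulated on the vertical axis. Genes past an adjusted p of 0.05 for the mean of both conditions are marked. They were chosen by the mean of both axes, so their place along the diagonal is no separate evidence of likeness.

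Genes higher after beads in efflux(+) cells included LTA, CSF2, GZMB and IL2RA. The labels used here give 12 h only for the stimulated libraries and no time in culture for the unstimulated ones. Effects of the beads therefore cannot be told apart from those of culture or handling time, here and below. Lymphotoxin alpha, LTA, was at 34.2 ± 11 CPM unstimulated and 699 ± 354 after beads (log2 fold change 4.36, adjusted p = 0.00571). The growth factor gene CSF2 went from 2.68 ± 2.34 to 202 ± 206 (6.28, adjusted p = 0.0196), GZMB from 35 ± 11 to 794 ± 484 (4.51, adjusted p = 0.0367), IL2RA from 71.9 ± 34.7 to 754 ± 378 (3.39, adjusted p = 0.0137), and the inhibitory receptor LAG3 from 108 ± 53.0 to 369 ± 80.5 (1.77, adjusted p = 0.0396). Genes that fell included the glucocorticoid-induced gene TSC22D3 (−4.04, adjusted p = 0.0254), the anti-proliferative gene BTG1 (−1.66, adjusted p = 0.0153), the vesicle protein gene CALY (−5.31, adjusted p = 0.00571) and the heat shock chaperone DNAJB1 (−3.84). HSPA1A fell by 4.19 (adjusted p = 0.00890) and HSPA1B by 4.50, though these near-identical copies are uncertain as single genes. The chemokine CCL3 rose (3.21), with the same caution for its copy CCL3L1.

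In efflux(+) cells 500 genes passed in edgeR after beads, 244 higher and 256 lower, with 2632 at an unadjusted p under 0.05. Leaving out unstimulated libraries 1, 2 and 3 gave 272, 154 and 357 genes, and leaving out stimulated libraries 1, 2 and 3 gave 155, 43 and 52. With a replicate block by accession order, chosen after the data were seen, 946 genes passed. Without both unstimulated libraries of number 3 the count was 1964. LTA, CALY, CALR and the interferon-induced GTPase GBP4 (2.03, adjusted p = 0.00320) passed in every alternative. IFNG (110 ± 64.2 to 274 ± 153 CPM; adjusted p = 0.316), TNF (372 ± 514 to 325 ± 114; −0.19, adjusted p = 0.959), IL2 (9.02 ± 6.30 to 18.2 ± 12.7; adjusted p = 0.563), CD69 (−2.53, adjusted p = 0.219) and ABCB1 (−0.88, adjusted p = 0.212) were not past the threshold. Without both unstimulated libraries of number 3, TNF rose by 2.11 (adjusted p = 0.0329). CD69 was at 633, 1308 and 11262 CPM in unstimulated efflux(+) libraries 1, 2 and 3, and its log2 fold change was −3.83 to −0.34 over all alternatives.

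Of the 9 lists called with beads in efflux(+) cells, ribosome biogenesis had the smallest adjusted p. It rose by a median of 0.93 (adjusted p = 2.9e-19, 0.291 with an estimated correlation), with 7 risen over all genes, such as NHP2 (1.68, adjusted p = 0.00890), WDR12 (1.54) and RRS1, and 36 of 46 over the list alone. Cholesterol and fatty acid synthesis had a median of 0.91 over 32 genes (adjusted p = 5.8e-10, 0.291 with an estimated correlation), with 9 risen, 0 fallen and 23 not past, and 13 risen over the list alone. The sterol genes FDFT1 (1.47, adjusted p = 0.0126), FDPS (1.38) and ACAT2 (1.35) were examples. Oxidative phosphorylation had a median of 0.37 over 45 genes (adjusted p = 4.0e-09, 0.458 with an estimated correlation), with CYC1, ATP5A1 and ATP5G1 risen and 7 risen over the list alone. Glycolysis had a median of 0.55 (adjusted p = 8.8e-05, 0.291 with an estimated correlation), with PFKP, ENO1, LDHB, GPI and PFKL risen and 9 risen over the list alone. For the unfolded protein response the median was 0.36 (adjusted p = 6.4e-04, 0.291 with an estimated correlation), with 6 risen such as CALR (1.32, adjusted p = 0.00576), DNAJB9 fallen, and 8 risen and 2 fallen over the list alone.

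Immediate-early and dissociation genes fell with beads in efflux(+) cells (median −2.30 over 34 genes, adjusted p = 1.9e-11, 0.291 with an estimated correlation), with 7 fallen over all genes, including JUND, FOSL2 and KLF6, and 22 over the list alone. Unstimulated efflux(+) library 3 had 6.82% of its counts in 9 immediate-early genes, against 0.179 and 0.256% in libraries 1 and 2, and without both unstimulated libraries of number 3 the list had a median of −1.28 (adjusted p = 2.4e-09). Quiescence genes fell (median −0.90, adjusted p = 0.00288, 0.291 with an estimated correlation), with BTG1, TSC22D3, KLF6 and PIK3IP1 fallen, LTB risen (3.02, adjusted p = 0.0258), and 2 risen and 10 fallen over the list alone. Effector cytokines rose (median 0.98 over 22 genes, adjusted p = 0.0325, 0.681 with an estimated correlation), with LTA, CSF2 and LTB risen, TNFSF9 fallen, and 4 risen and 3 fallen over the list alone. Without unstimulated efflux(+) library 1 the adjusted p was 0.0944 and without library 2 it was 0.0545. Fatty acid uptake and oxidation had a median of 0.23 over 21 genes (adjusted p = 0.0357, 0.291 with an estimated correlation), with FABP5 risen over all genes and over the list alone. Without unstimulated efflux(+) library 1 or 2, or stimulated efflux(+) library 1 or 3, that adjusted p was 0.104, 0.0538, 0.0513 and 0.0536.

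Of the 500 genes called with beads in efflux(+) cells, 493 had the same direction in efflux(−) cells, and the log2 fold changes of all tested genes had a Pearson correlation of 0.63. In efflux(−) cells LTA went from 23.9 ± 9.70 to 263 ± 142 CPM (3.46, adjusted p = 0.0282), IL2RA from 16.5 ± 5.69 to 260 ± 129 (3.98, adjusted p = 0.0186), CSF2 from 1.21 ± 0.794 to 66.8 ± 51.2 (5.86, adjusted p = 0.0459), and CD160 from 14.3 ± 1.64 to 81.0 ± 33.2 (2.50, adjusted p = 0.0282). ASB2, a ubiquitin ligase subunit gene, rose by 2.68 (adjusted p = 0.0153). MYADM, a membrane raft protein gene, fell from 527 ± 144 to 47.7 ± 8.67 CPM (−3.47, adjusted p = 0.00223), and the cholesterol exporter ABCG1 from 108 ± 51.3 to 6.88 ± 2.29 (−3.98, adjusted p = 0.0177). GZMB was at 91.8 ± 95.1 unstimulated and 307 ± 243 CPM after beads and did not pass (adjusted p = 0.409). IFNG (0.82, adjusted p = 0.620), TNF (0.95, adjusted p = 0.742), IL2 (2.41, adjusted p = 0.215), CD69 (−1.52, adjusted p = 0.540) and ABCB1 (−0.55, adjusted p = 0.557) did not pass either.

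In efflux(−) cells 112 genes passed in edgeR, 49 higher and 63 lower, with 2083 at an unadjusted p under 0.05. Of the genes risen in either kind of cell, 37 were shared (0.849 for independent lists), and of the fallen 53 (1.15 for independent lists). Such values leave out that libraries with neighbouring titles deviated together, and that both unstimulated libraries of number 3 stood apart. LTA, CSF2, IL2RA and FDFT1 were among genes raised in both, and HSPA1A, DNAJB1 and MAP1A among those lowered in both. Leaving out unstimulated libraries 1, 2 and 3 gave 13, 41 and 290 genes, and leaving out stimulated libraries 1, 2 and 3 gave 15, 3 and 3. With the replicate block by accession order the count was 334. MYADM passed in every alternative. Without both unstimulated libraries of number 3 the count was 1610.

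Cholesterol and fatty acid synthesis had the smallest adjusted p among rising lists in efflux(−) cells (median 0.71, adjusted p = 1.9e-08, 0.291 with an estimated correlation), with FDFT1, FDPS, ACAT2 and MSMO1 risen and 10 risen over the list alone. Immediate-early and dissociation genes fell (−1.90, adjusted p = 2.2e-12, 0.291 with an estimated correlation), with 4 members fallen over all genes, the heat shock genes HSPA1A, HSPA1B, DNAJB1 and HSP90AA1, and 18 over the list alone. Without both unstimulated libraries of number 3 the median was −1.07 (adjusted p = 1.9e-07). Oxidative phosphorylation rose (0.38, adjusted p = 4.0e-07, 0.509 with an estimated correlation), with 0 members past either way. Chemokines rose (1.46, adjusted p = 0.00145, 0.241 with an estimated correlation), with CCL3 risen, 6 risen over the list alone, and 0.0951 without both unstimulated libraries of number 3. Effector cytokines rose (1.11, adjusted p = 0.00683, 0.551 with an estimated correlation), with LTA and CSF2 risen and 7 risen and 2 fallen over the list alone.

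The remaining called lists in efflux(−) cells depended on single libraries. Egress genes fell (−1.22, adjusted p = 0.00145, 0.551 with an estimated correlation), with PLXDC1 fallen, 3 fallen over the list alone, and a median of −0.11 (adjusted p = 0.560) without unstimulated library 3. Ribosome biogenesis rose by a median of only 0.14 (adjusted p = 0.0231, 0.866 with an estimated correlation), with NHP2 risen over all genes and over the list alone, 0.267 without unstimulated library 3 and 0.818 without stimulated library 3. The unfolded protein response rose by 0.29 (adjusted p = 0.0231, 0.437 with an estimated correlation), with SDF2L1 risen, 3 risen over the list alone, 0.210 without unstimulated library 3 and 0.0535 without stimulated library 2. With the replicate block by accession order, camera also called chemokine receptors as lower (median −0.33, adjusted p from 0.119 to 0.0488, 0.397 with an estimated correlation) and fatty acid uptake and oxidation as higher (0.17, from 0.0548 to 0.0238, 0.242 with an estimated correlation).

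For single genes, few differences in the response to beads between efflux(+) and efflux(−) cells were called. In edgeR 0 genes passed for the interaction and 276 had an unadjusted p under 0.05, where 704 would be expected by chance. DESeq2 called 4, limma-voom 0 and limma on the deposited normalized values 0. Pairing also gave 0, with 1322 at an unadjusted p under 0.05. The unpaired number lies below that expected by chance, so the lack of calls there is no evidence of equal responses. CCND2, which drives entry into the cell cycle, had the smallest p: 241 ± 18.4 to 868 ± 361 CPM in efflux(+) cells and 309 ± 85.1 to 266 ± 61.7 in efflux(−) cells (interaction 2.07, SE 0.43, adjusted p = 1.0, or 0.145 with pairing). ZNF365, with 9 and 14 counts in unstimulated and stimulated efflux(+) cells against 315 and 1 in efflux(−) cells, and TMPPE (4.76) followed. In DESeq2 these 3 genes passed (adjusted p = 0.0247, 0.0433 and 0.0278) and in no other alternative. ENDOD1 (1.62) and the interferon-induced OAS3 (1.53) came next. The smallest p of a negative interaction was that of CD40LG (−3.23; 32 ± 22.5 to 6.30 ± 2.67 CPM against 4.30 ± 0.944 to 7.94 ± 2.32), and none of these passed in edgeR. For ABCB1 the interaction was −0.33 (SE 0.52).

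Lists of genes were called for the interaction at the preset correlation of camera only. Ribosome biogenesis genes rose further in efflux(+) cells, by a median of 0.62 (adjusted p = 1.1e-20, 0.291 with an estimated correlation). NOLC1, a nucleolar phosphoprotein gene, went from 213 ± 10.5 to 425 ± 114 CPM in efflux(+) cells and from 209 ± 23.7 to 228 ± 74.9 in efflux(−) cells, and TSR1 from 68.7 ± 14.7 to 146 ± 21.9 and from 65.1 ± 16.8 to 70.9 ± 22.6. Glycolysis genes followed by a median of 0.40 (adjusted p = 2.5e-04, 0.291 with an estimated correlation), with ENO1 going from 1130 ± 464 to 3329 ± 304 CPM in efflux(+) cells and from 1216 ± 374 to 1874 ± 241 in efflux(−) cells. In both lists 0 members passed over all genes, and both kept their call whichever library was left out.

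The other lists called for the interaction were less stable, each with 0 members past over all genes. Cell cycle genes had a median interaction of 0.66 (adjusted p = 0.00329, 0.490 with an estimated correlation), with 1 risen over the list alone and an adjusted p of 0.267 without unstimulated efflux(−) library 3, where the median was 0.0744. It was 0.13 without both unstimulated libraries of number 3 (adjusted p = 0.400). Quiescence genes had −0.44 (adjusted p = 0.00769, 0.291 with an estimated correlation), with 0.149 without unstimulated efflux(−) library 1 and 0.0886 without unstimulated efflux(+) library 3. Interferon response genes had 0.16 (adjusted p = 0.0346, 0.695 with an estimated correlation), with 2 risen over the list alone. Its value was 0.169, 0.349 and 0.725 without unstimulated efflux(+) libraries 1 and 2 and efflux(−) library 3, and 0.169, 0.0828 and 0.15 without stimulated efflux(+) libraries 1 and 3 and efflux(−) library 3. The interferon median turned to −0.0558 without unstimulated efflux(−) library 3. The unfolded protein response had 0.22 (adjusted p = 0.0346, 0.474 with an estimated correlation). There the value was 0.411, 0.138 and 0.0561 without unstimulated efflux(−) library 1 and efflux(+) libraries 2 and 3, and 0.0971, 0.163, 0.0646 and 0.0787 without stimulated efflux(+) libraries 1 and 2 and efflux(−) libraries 1 and 3.

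With pairing, 7 further lists passed for the interaction in camera at the preset correlation, again with 0 members past over all genes, and none of them passed with an estimated correlation (paired adjusted p from 0.279 to 0.756). Sterol and fatty acid synthesis (median 0.27 unpaired, adjusted p from 0.0987 to 0.0127) and egress genes (0.88, from 0.0927 to 0.00188) were positive. Chemokines (−0.69, from 0.0829 to 0.00377), MAIT markers (−0.71, from 0.0695 to 0.0183), NK and innate receptors (−0.33, from 0.126 to 0.0307), CD4+ and regulatory T cell markers (−0.59, from 0.0987 to 0.0320) and immediate-early and dissociation genes (−0.40, from 0.640 to 0.0456) were negative.

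The residency list was not called between efflux(+) and efflux(−) cells (median 0.15 for the averaged difference, adjusted p = 0.305), and members moved in both directions. CCL20, CCR6 and ITGAE had risen and RGS1, PDCD1 and LITAF had fallen, with 24 members not past. CXCR6, a liver and tissue homing receptor, was at 505 ± 248 against 432 ± 333 CPM at rest, and CD69, used in the gate, did not pass (0.91 for the averaged difference). The inhibitory receptor list was also split (median −0.03, adjusted p = 0.903), with CD160 risen and the receptors CTLA4 and PDCD1 and the factor TOX fallen. CD8A (−0.35) and CD8B (−0.48) did not differ past the threshold, and neither did IFNG (0.42) or TNF (0.93, with pairing adjusted p = 0.0263). The T cell receptor activation list was not past it for the averaged difference (0.42, adjusted p = 0.0695, with pairing 0.00183, or 0.372 with an estimated correlation), nor with beads in efflux(+) (−0.19, adjusted p = 0.863) or efflux(−) cells (−0.24, adjusted p = 0.969). Markers of B and plasma cells, myeloid cells, erythroid cells and stroma had adjusted p from 0.407 to 0.838 between efflux(+) and efflux(−) cells at rest, and from 0.0772 to 0.666 with pairing. Single members differed with pairing: CD74 of the B cell list was lower in efflux(+) cells at rest (−1.26, adjusted p = 0.0157). HBB of the erythroid list, whose median was −2.0 over 5 genes at rest, was lower for the averaged difference (−1.54, adjusted p = 0.0482 with pairing).

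Immediate-early genes set the unstimulated libraries of number 3 apart from all others. FOS, a transcription factor induced within minutes of a stimulus, was at 22100 and 9315 CPM in the efflux(+) and efflux(−) libraries of that number, and at 87.1 to 372 in the other unstimulated libraries. The summed share of 9 such genes was 6.82% and 3.38%, against 0.109 to 0.256% in the other unstimulated and 0.0883 to 0.115% in the stimulated libraries. TNFRSF9, which encodes the activation marker 4-1BB, was lower in them (26 and 37 against 482 to 1389 CPM in the other unstimulated libraries). Stimulated libraries held 148 to 1294 CPM of it, so unstimulated numbers 1 and 2 were not below them for this marker. IL2RA went the other way, with means of 71.9 and 754 CPM before and after beads in efflux(+) cells and 16.5 and 260 in efflux(−) cells. Whether cells of unstimulated numbers 1 and 2 were already activated was not tested. The unstimulated libraries of number 3 were also less deep, with totals of 19680387 and 16286040 counts against 31054564 to 33954253. Comparisons of stimulated with unstimulated cells were therefore also given without the unstimulated libraries of number 3, which leaves numbers 1 and 2 as the unstimulated side.

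**Figure D4:**
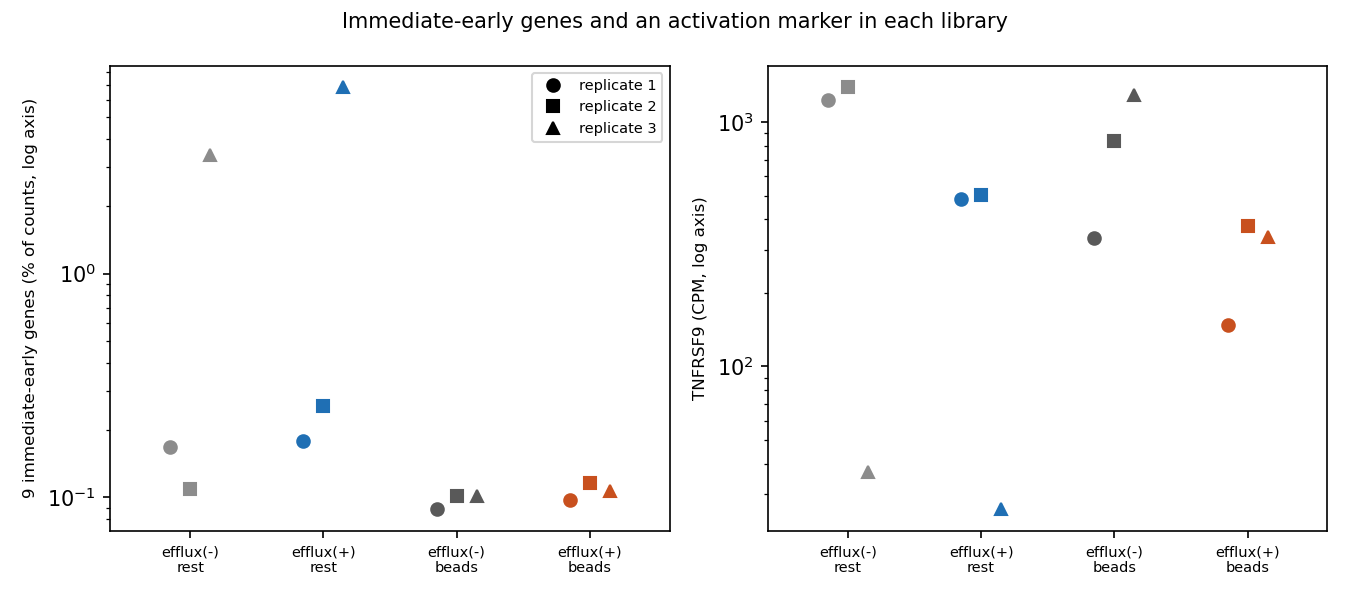
Share of counts in immediate-early genes and level of an activation marker in each library (log axes), by group and replicate number. The unstimulated libraries of number 3 lie far above the others for immediate-early genes and far below the other unstimulated ones for the marker.

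Limits of these comparisons follow from their size. The replicates are called biological in the design text and donors are not given, so all p-values measure the spread between these samples. With 3 against 3 libraries, complete separation of a gene such as ABCB1 is expected by chance in 10% of genes with no difference, and no exact rank test can reach less. Lists were called mainly under the preset correlation of camera: of 186 tests 58 passed, while 2 passed with an estimated correlation, both for NK and innate receptors.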

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

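The tests of a MAIT cell share, of NK cells, of depth and handling for immediate-early genes, and of a weaker activation for ribosome genes were chosen after the results were seen. Those of further activation genes, of ribosome genes without the unstimulated libraries of number 3 or at equal depth, and of splits of the libraries were written down before they were run.

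Attention was drawn by gene lists whose response to beads differed between efflux(+) and efflux(−) cells in camera at its preset correlation, while 0 genes passed in edgeR and 4 in DESeq2. The median log2 interaction was 0.62 for ribosome biogenesis, 0.40 for glycolysis, 0.66 for cell cycle, −0.44 for quiescence and stemness, 0.16 for interferon response and 0.22 for the unfolded protein response. Ribosome biogenesis and glycolysis kept their call whichever library was left out, and the other lists did not. With an estimated correlation none of them passed (camera adjusted p = 0.291, 0.291, 0.490, 0.291, 0.695 and 0.474 in the same order).

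For the larger rise of ribosome biogenesis genes with beads in efflux(+) cells, the unstimulated replicate 3 libraries were weighed as a source. Without them the median interaction was 0.58 (camera adjusted p = 1.4e-13; 1.6e-29 to 0.291 over all alternatives, the highest with an estimated correlation), which speaks against that source. At equal depth it was 0.62 (camera adjusted p = 1.1e-20), which speaks against a difference in sequencing depth. For a weaker activation of all genes in efflux- cells, the T cell receptor activation list had a median interaction of −0.31 (median absolute deviation 0.67), and the test cannot tell. Growth-related genes may respond apart from activation genes, and the cause remains open.

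Higher MAIT markers in efflux(+) cells could come from a larger share of MAIT cells in the efflux+ gate, as MAIT cells often carry CD8 as an alpha-alpha dimer. The log2 ratio of CD8B to CD8A was lower in efflux(+) cells by a mean of −0.22 over 6 pairs (SD 0.55, lower in 4 pairs; exact two-sided sign-flip p = 0.406, smallest possible 0.0313), and the test cannot tell. This p takes the 6 pairs as independent. Libraries of the same number deviated together across stimulation, so the p and its smallest possible value may be too small. Bulk libraries do not separate more MAIT cells from higher expression per cell. NK or innate lymphoid cells without CD3 in the efflux+ gate, which CD3 enrichment and the CD8 gate should deplete, were weighed with 5 NK genes, whose paired median was 0.80 (median absolute deviation 1.79). TYROBP was higher (2.60, adjusted p = 0.0155 in edgeR with pairing; 10.5 ± 15.5 against 1.44 ± 1.01 CPM at rest), SH2D1B (107 counts against 0 at rest, 61 against 24 after beads), KLRF1 (0.80), FCGR3A (−1.14) and FCER1G (−0.25) were not past the threshold, and the test cannot tell.

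High immediate-early genes in the unstimulated libraries of number 3 were weighed against a difference in sequencing depth. The stimulated libraries, of like depth, had at most 0.115% of counts in these genes against at least 3.38%, which speaks against depth. Activation of the cells through the T cell receptor would raise further activation genes. Those weighed were the activation list without immediate-early genes and without genes such as TNFRSF9 and IL2RA. Their median difference from numbers 1 and 2 was −0.52 over 27 genes (median absolute deviation 1.65). Of these 13 were higher, such as GADD45B (2.62) and NFKBIA (2.07), and 14 lower, such as TNFRSF18 (−3.77) and IRF4 (−2.73). The genes were not all late ones and moved both ways, so the test cannot tell. For handling of the tissue before sorting, heat shock genes made up at least 0.759% of counts against at most 0.795% in the other unstimulated libraries, and the test cannot tell either. A difference in the time between sorting and lysis might act on both sets of genes, and no label used here records it.

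Counts of calls were set against other splits of the same libraries. At rest 3 of 10 splits, the real one included, gave 29 or more genes. The highest others gave 1038 and 346 genes and keep both unstimulated libraries of number 3 in 1 group, while the 3 other splits that part every pair gave 0. After beads, and for stimulation in efflux(+) and efflux(−) cells, 1 of 10 splits reached the real count each time, and every other split gave 0; with 10 splits a share under 0.05 cannot be reached. For the averaged difference 2 of 100 splits reached 183 (highest other 231). This argues against a random division of these libraries only if unstimulated and stimulated libraries are independent. For the interaction all 100 of 100 splits reached the real count of 0. No count can be lower, so this comparison cannot decide anything.

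With the libraries paired, swaps of the labels within pairs were the splits. The real labels alone, 1 of 4 swaps, reached 287 genes at rest and 931 after beads, and the others gave 0. For the averaged difference 1 of 32 swaps reached 1212 (highest other 31). For the interaction 32 of 32 reached the real count of 0, as any swap must, so nothing follows from it. The highest there, 1212, is the swap that turns the interaction into the averaged difference. The correlation of efflux differences at rest and after beads, computed from mean log2 CPM, was reached in 1 of 200 splits (0.55; highest other 0.42). Genes are not independent replicates, so this share and not a p across genes is given. All shares over both conditions take unstimulated and stimulated libraries as independent. Libraries of the same number deviated together across stimulation, so these shares may be too small.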

How the results depend on the processing

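Fits without the unstimulated libraries of number 3 or with only those, thinning, and the accession-order block were chosen after the data were seen. Fits with only those hold 1 unstimulated library per group and take the spread from the other groups, so they do not show what stimulation does. Causes of the changes below were not tested.

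Genes between efflux(+) and efflux(−) cells at rest (29 in edgeR) were 193 with the DESeq2 Wald test, 11 with limma-voom, 287 with the replicate block, 1 with only the 6 libraries compared, 50 without both unstimulated libraries of number 3, 236 with that and the block, and 2 to 33 with a library left out. After beads (8) they were 312 with DESeq2, 1 with limma-voom, 23 with no filter, 21 with the stricter filter, 931 with the replicate block, 374 with only the 6 libraries compared, 33 with limma on the deposited normalized values, 19 when thinned, and 1 to 8 with a library left out.

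Genes of stimulation in efflux(+) cells (500) were 1343 with DESeq2, 64 with only the 6 libraries compared, 1964 without both unstimulated libraries of number 3, 2142 with only those, and 43 to 357 with a library left out. In efflux(−) cells (112) they were 768 with DESeq2, 69 with limma-voom, 9 with only the 6 libraries compared, 1610 without both unstimulated libraries of number 3, 1409 with only those, and 3 to 290 with a library left out. The interaction (0) gave 4 genes in DESeq2. The averaged difference (183) gave 542 in DESeq2, 1212 with the replicate block, 425 without both unstimulated libraries of number 3, 1202 with that and the block, and 97 to 269 with a library left out.

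A replicate block by the order of accessions gave 78 genes at rest, 97 after beads, 946 and 334 for stimulation in efflux(+) and efflux(−) cells, 0 for the interaction and 336 for the averaged difference. It changed no call of a gene named for stimulation. Of the lists called for stimulation all 9 in efflux(+) cells and all 8 in efflux(−) cells stayed, and 0 passed with an estimated correlation.

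List calls (58) were 2 with an estimated correlation in camera and 10 with fry. Of the list calls 35 were kept with every library left out and 23 lost in at least 1 such fit. The pairing by title numbers changed list calls of the efflux comparisons from 41 to 57 of 124, and apart from the values printed beside the results it changed no other call of them; every gene called without pairing was called with it.

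Directions turned round mostly for genes not past the threshold. At rest ABCC1 (0.01) was −0.00198 with size factors of DESeq2, −0.00214 with DESeq2, −0.10 without both unstimulated libraries of number 3, −0.0886 with that and the block, and −0.21 to 0.24 with a library left out. CXCR6 (0.22) was −0.29 without those libraries, −0.45 with the block as well, and −0.26 to 0.92 with a library left out. Left-out ranges also crossed 0 at rest for CD69 (−0.76 to 3.12), IFNG (−0.42 to 1.02), TNF (−0.78 to 3.25) and CD8A (−0.65 to 0.0351), and after beads for IL17A (−0.37 to 2.31), ABCC1 (−0.10 to 0.12) and IL2 (−0.26 to 0.90).

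For stimulation in efflux(+) cells TNF (−0.19) was 0.77 with limma-voom, 0.82 with limma on the deposited values, 2.11 without both unstimulated libraries of number 3 (adjusted p = 0.0329 in edgeR, a gained call), 0.92 with the accession-order block, and −0.68 to 2.11 with a library left out; PDCD1 (−0.30) was 0.0697 without those libraries and −0.60 to 0.0688 with a library left out. In efflux(−) cells IFNG (0.82) was −0.0858 and TNF (0.95) −0.30 with only the unstimulated library of number 3 (n = 1), with left-out ranges of 0.16 to 1.68 and 0.45 to 2.72. CD69 (−1.52) was 0.21 without both unstimulated libraries of number 3 and −1.98 to 0.22 with a library left out. The immediate-early and dissociation list at rest had an adjusted p of 3.0e-06 to 0.909 with a library left out, with its direction turned round at the upper end. Effector cytokines in efflux(+) cells had 4.2e-04 to 0.0944, and 0.876 with the direction turned round with only the unstimulated library of number 3, and those in efflux(−) cells 0.948 in that fit. With a library left out, medians of called lists crossed 0 for ABC transporters (−0.18 and −0.0895) and immediate-early and dissociation genes (−0.42) at rest, for ribosome biogenesis in efflux(−) cells with beads (−0.00836), for interferon response in the interaction (−0.0558), and for cytokine receptor genes (−0.0153) and immediate-early and dissociation genes (−0.0606) in the averaged difference.

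Among all alternatives 69 of 126 counts stayed the same and 57 moved, 2592 of 3091 values of genes stayed, 399 were weaker, 66 stronger and 34 reversed, and of 747 list values 567 stayed, 177 were weaker and 3 reversed. ABCB1 passed in all 20 alternatives at rest, all 18 after beads and all 25 for the averaged difference (highest adjusted p 0.0369, 0.00657 and 1.2e-04). The correlation of efflux differences across genes (0.50) was 0.71 with the stricter filter and 0.51 with the replicate block.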

Other observations

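These observations were made after the data were seen, and the list of HLA class II genes was chosen then. Most of 13 HLA class II genes, with CD74 and CIITA counted among them, had lower estimates in efflux(+) cells, with a median log2 fold change of −1.61 at rest, −1.99 after beads and −1.66 for the averaged difference. HLA-DOB went the other way (0.21, 0.10 and 0.16), and no list test was run. In edgeR 7 of them had fallen for the averaged difference (0 risen), 0 at rest and 1 after beads, and with pairing 12, 11 and 9 had fallen. For the averaged difference HLA-DRA differed by −2.19 (adjusted p = 0.00831), HLA-DMA by −1.58 (adjusted p = 0.00652) and HLA-DPA1 by −1.38 (adjusted p = 0.0182), while CD74 (−1.01, adjusted p = 0.141, with pairing 0.00362) and the class II regulator CIITA (−1.52, adjusted p = 0.15, with pairing 0.0128) passed only with pairing. HLA genes are polymorphic and share sequence, so reads counted on 1 reference are uncertain for single genes. At rest CD74 was at 615 ± 204 against 1471 ± 519 CPM, the B cell gene MS4A1 at 13.1 ± 7.72 against 13.5 ± 2.92 and the monocyte gene CD14 at 0.754 ± 0.374 against 1.03 ± 0.624, with CD3 enrichment and a CD8 gate before sequencing. No explanation was tested for these genes.

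The averaged difference paired higher ITGAE (2.58, adjusted p = 0.0147) and HOPX (2.00) with lower PDCD1 (−1.40), TOX (−1.15) and CTLA4 (−2.60). Of these, ITGAE and PDCD1 belong to the residency list, which was not past the threshold as a whole (median 0.15, adjusted p = 0.305). No explanation was tested.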
